A study of Mus musculus with 4 samples.

How the data were processed

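Group 3 innate lymphoid cells (ILC3) are RORγt-dependent lymphocytes that lack antigen receptors and make IL-17 and IL-22 in the gut. Per the labels' protocols, CCR6-positive ILC3 were sorted from the small intestinal lamina propria of Nr1d1+/+ and Nr1d1-/- mice. The gate kept live cells of lymphocyte size with intermediate CD45 that carried CD90.2 and CCR6. It excluded cells with CD3ε, CD5, CD19, TCRβ, KLRG1 or NKp46. RNA was purified with a spin-column kit, amplified with a whole-transcriptome kit for picogram amounts, labelled with biotin and hybridised to 1-colour arrays, per the labels' protocols. There were 2 arrays of each genotype, called WT 1, WT 2, KO 1 and KO 2 after the number in their titles. Nothing says that the arrays of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

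The authors deposited 1 table with 27172 probe sets and a linear intensity for each array. The submitters' processing notes name RMA, which corrects the background, normalises arrays between each other and summarises the probes of a set, without a version. RMA usually gives log2 values, but the deposited intensity values ran from about 6.22 to 13609, so log2 was taken before any test, as had been planned for that case. The genome build, scan date and slide are not given in the sources used here. The table holds neither background nor detection values, so what lies above background was not known, and a difference between dim genes understates the true fold where a gene lies near the floor. The number of arrays limits the precision.

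Probe sets were named from GEO's platform annotation. Exactly 1 gene symbol was listed for 23521 probe sets and several for 1820, and 1831 were not in the annotation used. Of those with 1 symbol, 23328 matched the RefSeq gene table of GRCm38.p6 by gene identifier, which changed 0 symbols. That table served only for names and for the order of neighbouring genes, and no coordinates are given. The brightest probe set stood for each of the 1082 genes with more than 1, which left 22180 genes. Genes whose mean over the 4 arrays lay under the 30th percentile (log2 5.61) were left out, and 15526 were tested. Rorc and the other genes without a probe set of their own were not analysed here.

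Groups were compared with limma 3.58.1 (lmFit and eBayes, without trend or robust option) in R 4.3.3 on genotype alone. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and the threshold was an adjusted p of 0.05. Adjusted p-values of single genes below come from this fit unless another setting is named. With 2 residual degrees of freedom per gene, the moderated test borrowed 6.19 prior degrees of freedom and a prior SD of 0.20 from all genes. Differences are on the log2 scale, knockout minus wild type, with their moderated standard error (SE).

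Before the data were examined, 30 gene lists with 798 entries were fixed from textbook knowledge, and 714 of the entries had a probe set of 1 symbol. The lists covered clock genes, ILC3 functions, metabolism, stress, the cell cycle and markers of other cell types. The 29 lists with at least 5 tested genes were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move, on balance, one way and does not compare them with other genes.

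Genes were named by a rule fixed at the same time. It took Nr1d1 and its neighbour Thra, the 12 genes with the largest difference past the threshold in each direction (without predicted or family names), up to 6 members past the threshold and 4 others of largest difference in each list, and Il17a, Il17f, Il22, Rorc, Nfil3 and Arntl. Genes named outside it are said to be so.

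On 20 simulated data sets with the same 15526 genes and 2 arrays per group, the fit recovered 27.5% of genes changed 2-fold and 97.8% of those changed 4-fold, with 7.4 false calls per set and 0 calls of the wrong sign. Simulated errors were independent between genes and had the same spread in all 4 arrays. In the data KO 1 stood apart, so 7.4 does not measure the false calls among the real ones. A simulated list of 20 genes shifted by 0.5 was called in 20 of the 20 sets with the preset correlation and in 0 with an estimated one. So the estimated correlation had no power for a shift of that size in these simulated sets. Over the 7 lists called with the preset value in the data, the estimate ranged from 0.011 (cell cycle) to 0.63 (clock genes with ROR elements). It was 0.58 for class II presentation and 0.42 for immediate early genes. The preset value was not tested at such correlations, where its p-values may be too small. It called the epithelial list (estimate 0.81 over all 4 arrays) lower without WT 1 and higher without WT 2. The simulation therefore cannot decide between the preset and the estimated results for the 7 lists.

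The alternatives were quantile normalisation again, centring of each array on its median, no filter and a filter at the 50th percentile, the mean of a gene's probe sets, an intensity trend, the robust option, array weights, the replicate number as a block, log2(value + 16), each array left out in turn, an adjusted p of 0.10, all probe sets tested alone and an unmoderated linear model. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.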

Results

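Nr1d1 encodes REV-ERBα, a nuclear receptor that represses genes with ROR response elements, among them genes of the circadian clock. The arrays measured RNA of CCR6+ ILC3 from the small intestine of 2 wild-type (WT) and 2 Nr1d1-/- (KO) samples, and the only comparison of the design was between the genotypes. The median intensity over all probe sets was 85.1 in WT 1, 82.9 in WT 2, 81.3 in KO 1 and 81.1 in KO 2. The upper quartile was 238, 246, 211 and 247 in the same order, so KO 1 was the dimmest array there. Across the tested genes, which are not independent replicates, log2 values of WT 1 and WT 2 correlated with r = 0.979 and those of KO 1 and KO 2 with r = 0.965. Pairs across genotypes ranged from 0.944 to 0.975, and the lower of these held KO 1. KO 2 correlated more closely with WT 1 (0.975) and WT 2 (0.974) than with KO 1.

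The targeted gene was lower in both KO arrays. Nr1d1 measured 10.85 ± 0.07 (log2, SD, n = 2) in WT and 9.69 ± 0.01 (n = 2) in KO arrays, a difference of −1.16 (SE 0.18, 95% confidence interval −1.56 to −0.75). The mean intensity of its single probe set in KO arrays was 44.8% of that in WT arrays. Its adjusted p of 0.051 missed the threshold narrowly, and 7 of the 13 refitted settings without pairing put it past 0.05, with adjusted p-values from 0.0075 to 0.13. The labels do not say which part of the gene was removed and the position of its probes was not used, so the remaining signal neither measures intact transcript nor checks the deletion. Thra, the thyroid hormone receptor gene that overlaps the 3′ end of Nr1d1 on the other strand, differed by −0.99 (SE 0.22, adjusted p = 0.16).

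Genes higher in KO ILC3 were led by a second copy of the IL-22 gene, a matrix metalloproteinase gene and Spon2. Iltifb, the near-identical copy of Il22, rose by 4.02 (SE 0.28, 16.2-fold, adjusted p = 0.0022), from 4.64 ± 0.61 in WT to 8.65 ± 0.18 in KO arrays (log2, SD, n = 2 each). The WT values lie below the filter level of 5.61, so the fold rests on values near the floor of the table. The matrix metalloproteinase Mmp9 rose by 3.28 (SE 0.19, 9.69-fold, adjusted p = 9.2e-04) and Spon2, which encodes a secreted extracellular matrix protein, by 3.05 (SE 0.23, 8.26-fold, adjusted p = 0.0022). Bank1, a scaffold protein of B cell receptor signalling, rose by 2.17 (4.51-fold, adjusted p = 0.0060). The other genes of the 12 with the largest rise were Myl10 (2.09), the lectin-like receptor gene Klri2 (2.07), Srgap3 (1.96), the galactosyltransferase gene B3galt2 (1.86), Rnf144b (1.78), the growth factor gene Bmp4 (1.74), Zfp618 (1.61) and the neutrophil-attracting chemokine gene Cxcl3 (1.61), with adjusted p-values between 0.013 and 0.045.

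Genes lower in KO ILC3 included those of a calcium channel subunit, the enzymes Dgat2 and Plb1 and a neuropeptide receptor. Cacna1g, which encodes a T-type calcium channel subunit, fell by 3.33 (SE 0.18, adjusted p = 7.5e-04), from 10.90 ± 0.06 to 7.58 ± 0.02 (log2, SD, n = 2 each). The triglyceride-synthesising enzyme gene Dgat2 fell by 2.62 (SE 0.25, adjusted p = 0.0064), and the phospholipase gene Plb1 fell by 2.47 (SE 0.18, adjusted p = 0.0022). Vipr2, a receptor for vasoactive intestinal peptide, fell by 1.87 (SE 0.20, 3.64-fold, adjusted p = 0.013), and the vasoactive peptide gene Adm by 2.19 (SE 0.23, adjusted p = 0.013). S100g, a calcium-binding protein of gut epithelium, fell by 2.89 (SE 0.21, adjusted p = 0.0022). The other genes of the 12 with the largest fall were Ndnf (−2.79), the adhesion molecule gene Dscam (−2.39), Tmem150c (−2.38), BC018473 (−2.10), the trypsin gene Prss2 (−1.996) and Ms4a6b (−1.98), with adjusted p-values between 0.0032 and 0.021. The epithelial gene Reg3b measured 6.69 in WT 1, 11.31 in WT 2, 6.14 in KO 1 and 8.74 in KO 2. S100g measured 9.42, 8.96, 6.37 and 6.23 in the same order.

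**Figure D1:**
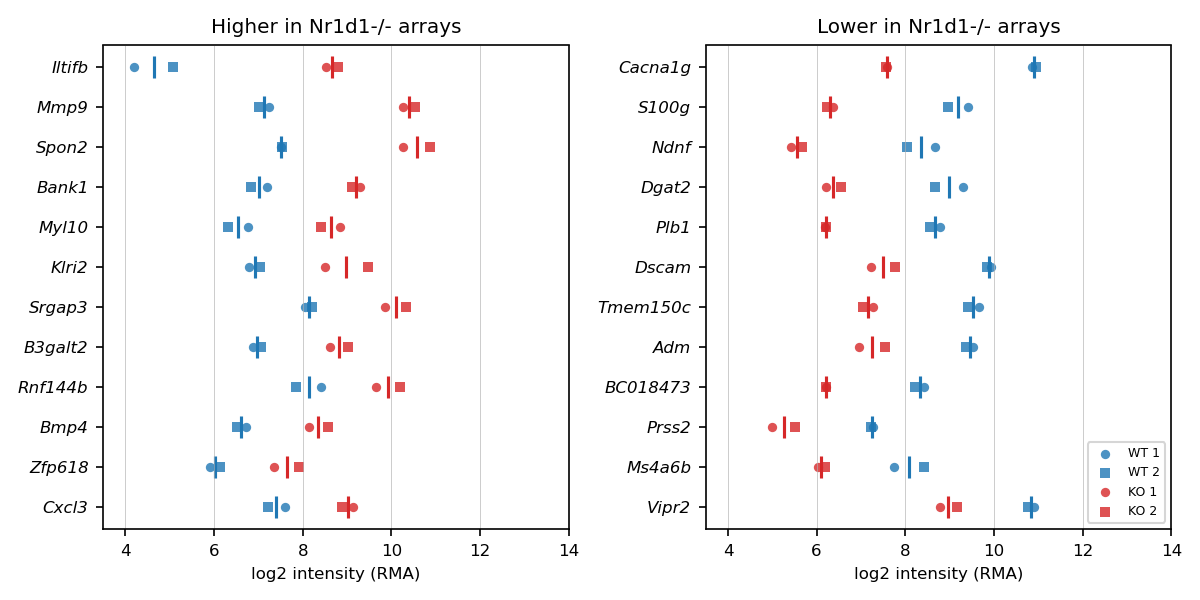
Log2 intensity of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) in Nr1d1-/- CCR6+ ILC3. Blue marks are WT and red marks KO arrays, circles are replicate 1 and squares replicate 2, and vertical ticks are group means of 2 arrays; in each gene both KO arrays lie on one side of both WT arrays, as for Cacna1g at 7.59 and 7.56 against 10.86 and 10.94.

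In all, 46 of 15526 genes passed, 18 higher and 28 lower in KO, with folds from 2.30 to 16.2. At an unadjusted p under 0.05 there were 1451 (416 higher and 1035 lower), and the median difference of all genes was −0.08. Of all genes, 182 differed at least 2-fold with both KO arrays beyond both WT arrays, 58 higher and 124 lower. Separation at any size held for 40.6% of genes, where chance gives 33.3%. The called genes that stayed past the threshold in each of the 14 refitted settings were Iltifb, Mmp9, Spon2, Bank1, Cacna1g, S100g, Ndnf, Dgat2, Plb1, Dscam, Tmem150c and BC018473, 12 in all. Without the filter, 12 genes passed, and with a second quantile normalisation 24. An unmoderated linear model, which has 2 residual degrees of freedom per gene, called 0 genes after adjustment and 978 at an unadjusted p under 0.05. The count depended on single arrays: it was 156 without WT 1 (42 higher and 114 lower), 79 without WT 2 (41 and 38), 102 without KO 1 (52 and 50) and 1800 without KO 2 (454 and 1346). So the excess of lower genes did not hold without WT 2 or without KO 1, and with centred arrays 31 genes were higher and 33 lower. The count of separated genes at least 2-fold apart was 300 without WT 1 and 538 without KO 2.

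Clock genes that REV-ERBα is known to repress were higher in KO ILC3 as a group with camera's preset correlation. All 6 tested members of the list of clock genes with ROR elements had a positive difference, with a median of 0.51 (camera, adjusted p = 3.8e-05, and adjusted p = 0.66 with an estimated correlation). Of the 6, 0 passed over all genes and 4 passed when adjusted over the list alone: Npas2 (0.95, SE 0.19), Nr1d2 (0.71, SE 0.23, but 0.43 without KO 2), Nfil3 (0.52, SE 0.19) and Cry1 (0.49, SE 0.18). Nr1d2 encodes REV-ERBβ, the paralogue of REV-ERBα, and Nfil3 a repressor needed for ILC development. Arntl, the clock activator BMAL1 and a known REV-ERBα target, differed by 0.18 (SE 0.22, adjusted p = 0.83), and by −0.085 without KO 2. The list of clock output genes driven by E-boxes and D-boxes was higher too, with a median of 0.44 over 12 genes (adjusted p = 5.9e-06, and adjusted p = 0.66 with an estimated correlation). Without WT 2 that median was 0.28. None of these passed over all genes (0 of 12), and adjusted over the list alone 4 were higher and 1 lower. The 4 were the PAR bZIP factor genes Dbp (1.11, SE 0.18, adjusted p over all genes 0.070) and Hlf (1.06, SE 0.21), Tspan4 (0.998, SE 0.19) and Ciart (0.86, SE 0.21). The lower one was Wee1 (−0.70), a cell cycle kinase gene named after its values were seen. Neither list passed with fry (adjusted p = 0.38 for both). The time of day of harvest is not given in the sources used here.

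Among type 17 genes, Il17a was higher in KO ILC3, while Il17f and Il22 did not pass over all genes. Il17a rose by 1.53 (SE 0.19, 2.89-fold, adjusted p = 0.021), from 6.80 ± 0.10 to 8.33 ± 0.19 (log2, SD, n = 2 each). Its call was lost with a second quantile normalisation (adjusted p = 0.062) and without the filter (0.072). Il17f differed by 1.30 (SE 0.25, adjusted p = 0.11), and passed when adjusted over the list alone. Il22 differed by −0.79 (SE 0.29, adjusted p = 0.46), with 11.24 ± 0.14 in WT and 10.45 ± 0.66 in KO arrays (log2, SD, n = 2 each). Single arrays moved it: it was −1.25 (adjusted p = 0.025) without KO 1 and −0.32 (0.27) without KO 2. Tnf differed by 0.59 (adjusted p = 0.38), and Il6st, the shared signalling subunit of the IL-6 receptor family, by −1.11 (SE 0.33, adjusted p = 0.34), with −0.53 without KO 1 and −1.68 without KO 2. As a list, the 15 type 17 cytokines and receptors did not pass (median 0.07, but −0.13 without KO 2 and −0.0037 without WT 2, adjusted p = 0.11), with 1 higher, 0 lower and 14 not passing over all genes and 2 higher over the list alone. The 25 type 17 transcriptional regulators did not pass either (median 0.02, but −0.14 without WT 2, adjusted p = 0.87). Of these, 0 passed over all genes, and over the list alone 2 were higher and 3 lower. Examples are the repressor gene Bcl6 (−1.03; −1.36 to −0.70 without single arrays), Batf (−0.91), Zbtb16, which encodes PLZF (−0.71), and the Ikaros family gene Ikzf3 (0.94). Rorc was not analysed here.

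**Figure D2:**
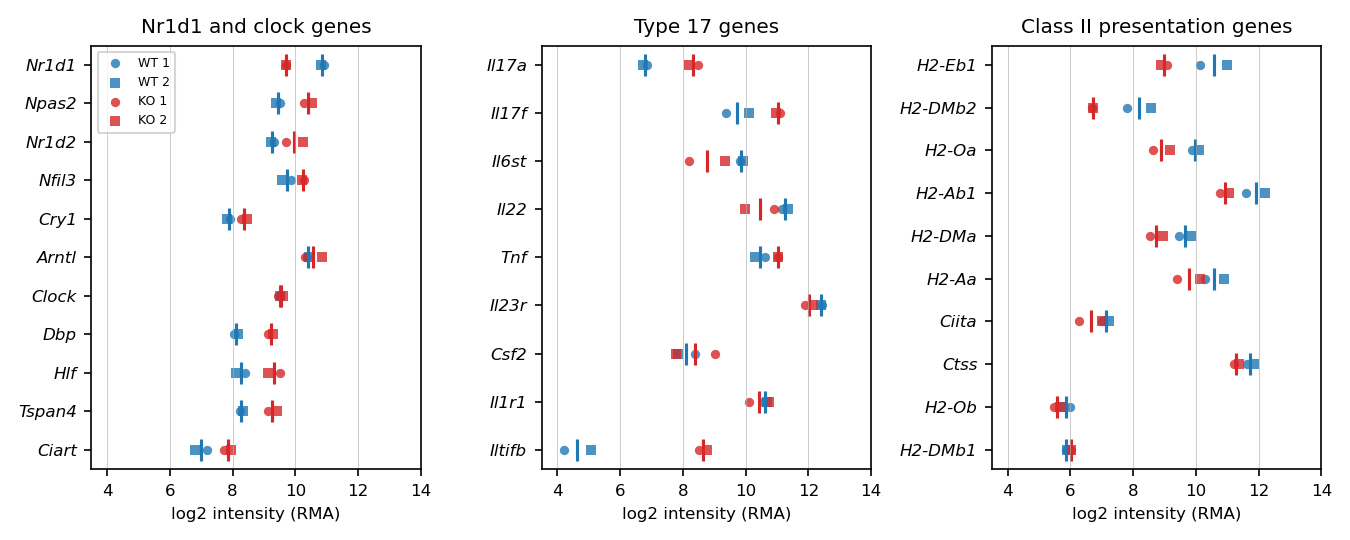
Log2 intensity per array of Nr1d1 with selected clock genes (left), of type 17 cytokine and receptor genes with Iltifb (middle) and of the 10 tested genes of class II antigen presentation (right). Blue marks are WT and red marks KO arrays, circles are replicate 1, squares replicate 2 and vertical ticks means of 2 arrays; Il17a lies at 8.47 and 8.20 in KO against 6.87 and 6.74 in WT arrays, and Il22 at 10.92 and 9.99 against 11.15 and 11.34.

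Genes of antigen presentation and markers of lymphoid tissue inducer cells, the CCR6+ ILC3 that organise lymphoid tissue, were lower in KO ILC3 as groups. These group calls rest on camera's preset correlation. The 10 tested genes of MHC class II presentation had a median difference of −0.88 (adjusted p = 4.8e-06, and adjusted p = 0.66 with an estimated correlation), and 9 of the 10 were negative. Without single arrays that median ranged from −1.13 to −0.60. Adjusted over all genes 0 passed, and adjusted over the list alone 6 were lower, among them H2-Eb1 (−1.57, SE 0.28), H2-DMb2 (−1.47, SE 0.26), H2-Oa (−1.09, SE 0.23) and H2-Ab1 (−0.98, SE 0.24; −1.29 to −0.67 without single arrays). The 17 tissue inducer markers had a median of −0.52 (adjusted p = 6.0e-05, and adjusted p = 0.66 with an estimated correlation), with 16 negative. That median was −0.25 without KO 1 and −0.83 without KO 2. Of the 17, 0 passed over all genes and 5 were lower over the list alone, among them the chemokine receptor genes Ccr7 (−1.04, SE 0.25; −1.39 to −0.69 without single arrays) and Cxcr5 (−0.83, SE 0.20), Nrp1 (−0.82, SE 0.19) and Icosl (−0.81, SE 0.18). Both lists missed the threshold with fry (adjusted p = 0.38). Markers of other cells that express class II genes were negative in the median but did not pass: the B and plasma cell list had a median of −0.22 over 10 genes (adjusted p = 0.096) and the myeloid and dendritic cell list of −0.27 over 19 (adjusted p = 0.054). Among these, Jchain differed by −1.65 (SE 0.43), Cd79b by −0.89 (SE 0.20) and Blk by −0.83 (SE 0.30), and Tyrobp by −0.81 (SE 0.27). Without single arrays Jchain ranged from −2.34 to −0.97, Blk from −1.22 to −0.44 and Tyrobp from −1.23 to −0.40. Over all genes 0 members of either list passed, and over the list alone 2 B and plasma cell genes were lower. The myeloid list passed with quantile normalisation again (adjusted p = 0.035), with centred arrays (0.041), without the filter (0.024), without WT 1 (0.0053) and without KO 1 (0.0050). The B cell list passed with the filter at the 50th percentile (median −0.53, adjusted p = 0.034), without WT 2 (0.0014) and without KO 1 (0.011), and its median was −0.052 without the filter.

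Genes of NKp46+ ILC3 and type 1 lymphocytes, a population that the gate excluded, showed 1 called member. Ncr1, which encodes NKp46, fell by 1.53 (SE 0.20, 2.89-fold, adjusted p = 0.027), and lost its call with a second quantile normalisation (adjusted p = 0.056) and without the filter (0.085). The other members of largest difference went both ways: Xcl1 (−1.32, SE 0.22), Ccl5 (−0.91, SE 0.21) and Klrb1c (−0.87, SE 0.36, but −0.26 without KO 1) were lower, and Klrk1 (1.03, SE 0.19) was higher, none of them past the threshold. As a list, the 23 genes had a median of −0.11 (0.0045 without KO 1, adjusted p = 0.31), with 0 higher, 1 lower and 22 not passing over all genes and 2 higher and 3 lower over the list alone. It passed without WT 2 (median −0.14, adjusted p = 0.0497). The 13 type 2 and ILC2 genes had a median of −0.26 (−0.14 without WT 1, adjusted p = 0.20) and 0 passing members, with Klrg1 at −1.08 (SE 0.28; −1.50 to −0.66 without single arrays), and passed without WT 2 (median −0.33, adjusted p = 0.031).

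Immediate early genes, which are induced quickly by cell stimulation and handling, were higher in KO arrays as a group with camera's preset correlation. Their median difference was 0.25 over 31 genes, 27 of them positive (adjusted p = 1.3e-08, and adjusted p = 0.66 with an estimated correlation). The median was 0.59 without WT 1, 0.14 without WT 2, 0.14 without KO 1 and 0.53 without KO 2. Over all genes 0 passed and over the list alone 1 did, the nuclear receptor gene Nr4a2 (0.85, SE 0.18). The largest difference was that of the phosphatase gene Dusp1 (1.05, SE 0.26), which measured 12.48 in WT 1 and 11.83 in WT 2 against 13.41 in KO 1 and 13.01 in KO 2. Cell cycle genes had a median of 0.12 over 35 genes (adjusted p = 0.0024, and adjusted p = 0.66 with an estimated correlation), with 0 passing members and the largest differences in Kif11 (0.75, SE 0.18) and Mcm3 (0.66, SE 0.20). That median was 0.0096 without KO 2 and 0.23 with centred arrays. Genes of cytosolic ribosomal proteins had a median of 0.07 over 49 genes (adjusted p = 0.0044, and adjusted p = 0.74 with an estimated correlation), with 0 passing members. Their median was 0.18 with centred arrays. None of the 3 lists passed with fry (adjusted p = 0.54, 0.49 and 0.49). The ribosomal call was also lost without the filter (adjusted p = 0.060) and without WT 1 (median −0.01, adjusted p = 0.19), and the median was 0.0094 without KO 2. Heat shock and chaperone genes did not pass (median 0.09 over 22 genes, but 0.0022 without WT 2, adjusted p = 0.062). Their 1 member past the threshold over the list alone was Hspb1 (0.92, SE 0.18, but 0.28 with the mean of its probe sets), and the list passed with the filter at the 50th percentile (adjusted p = 0.025).

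**Figure D3:**
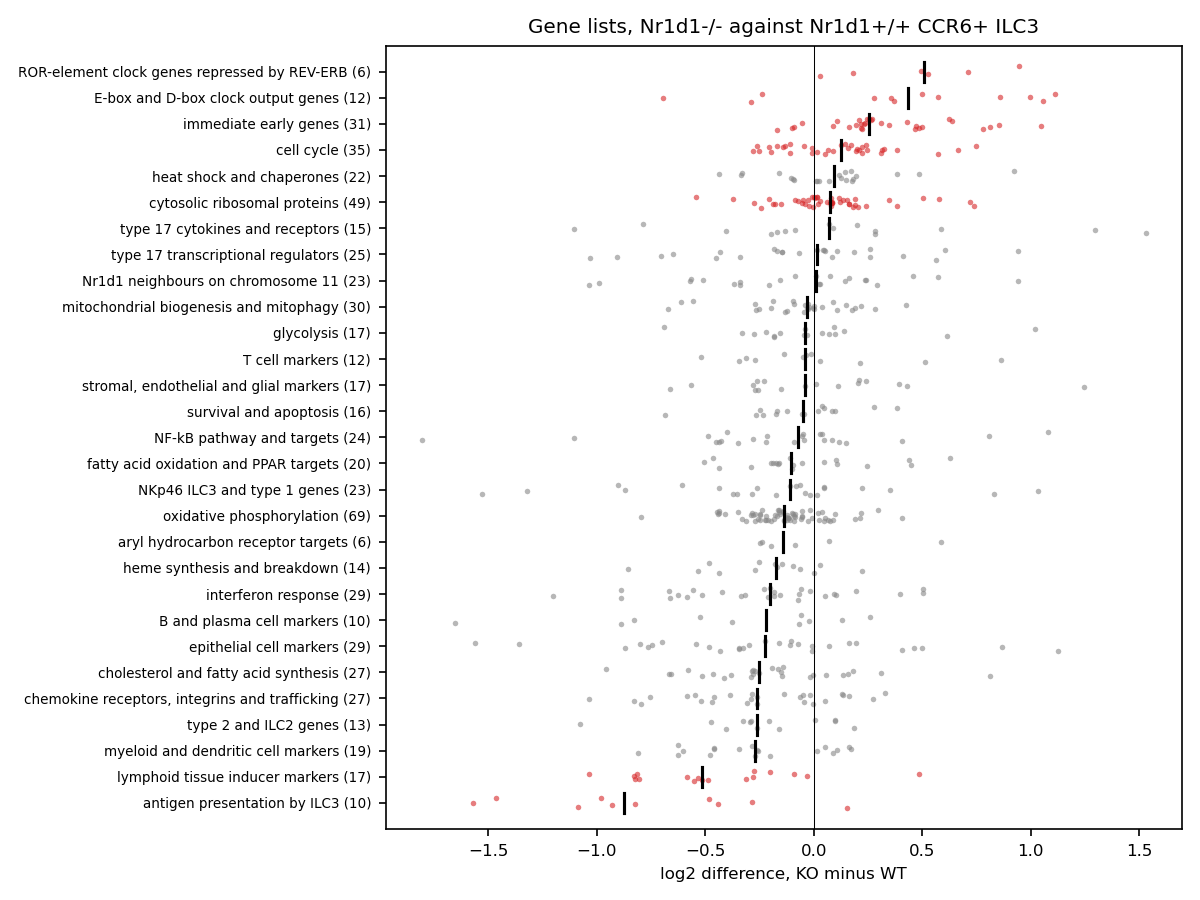
Log2 difference, KO minus WT, of each tested member (points) and the median (black bars) of the 29 gene lists tested, with the number of tested genes in brackets. Red lists passed camera with the preset correlation; antigen presentation (median −0.88) and lymphoid tissue inducer markers (−0.52) lie lowest and the 2 clock lists (0.51 and 0.44) highest.

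Metabolic lists did not pass. The 69 oxidative phosphorylation genes had a median of −0.14 (−0.058 without KO 1, adjusted p = 0.15), with Ndufb3 at −0.80 (SE 0.18), and the 27 genes of cholesterol and fatty acid synthesis of −0.25 (−0.049 without KO 1, adjusted p = 0.096), with Cyp51 at −0.96 (SE 0.22) and Sqle at −0.66 (SE 0.18). Both passed without the filter (adjusted p = 0.022 each), and with centred arrays their medians were −0.033 and −0.15. The median was −0.17 for 14 genes of heme synthesis and breakdown (−0.031 without KO 1, −0.40 without KO 2, adjusted p = 0.15), where Cpox differed by −0.85 (SE 0.18). It was −0.04 for 17 glycolysis genes (adjusted p = 0.49), where the phosphofructokinase gene Pfkp differed by 1.02 (SE 0.20). It was −0.03 for 30 genes of mitochondrial biogenesis and mitophagy (adjusted p = 0.89) and −0.10 for 20 genes of fatty acid oxidation (−0.020 without KO 1, adjusted p = 0.89). For 6 aryl hydrocarbon receptor targets it was −0.14 (−0.076 without WT 1, −0.21 without WT 2, adjusted p = 0.92). Over all genes 0 members of these lists passed, and over the list alone Cpox and Pfkp did. The medians of glycolysis and mitochondrial biogenesis changed sign when single arrays were left out.

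Of the signalling and trafficking lists, interferon response genes had a median of −0.20 over 29 genes (−0.038 without WT 2, −0.062 without KO 1, adjusted p = 0.096), with Bst2 at −1.20 (SE 0.22) and Ifit1 at −0.89 (SE 0.18) lower over the list alone. That list passed without the filter (adjusted p = 0.022) and without WT 1 (median −0.35, 5.1e-04). Chemokine receptors and integrins had a median of −0.26 over 27 genes (−0.057 without WT 1, −0.16 without KO 1, adjusted p = 0.054), with 4 lower over the list alone, among them Cxcr4 (−0.80, SE 0.20). That list passed with centred arrays (adjusted p = 0.041), without the filter (0.0099), with array weights (0.049) and without WT 2 (0.0018). The 24 genes of the NF-κB pathway had a median of −0.07 (0.031 without WT 1, adjusted p = 0.58), with Tnip3 (−1.81, SE 0.33) and Bcl2a1a (−1.11, SE 0.21) lower and Cxcl2 (1.08, SE 0.24) higher over the list alone, and passed without WT 2 (adjusted p = 0.0497). The 16 genes of survival and apoptosis had a median of −0.05 (0.044 without KO 1, adjusted p = 0.89), with Bcl2 at −0.69 (SE 0.20). Over all genes 0 members of these lists passed.

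Of the remaining markers, the 29 epithelial genes had a median of −0.22 (adjusted p = 0.82), and single arrays set it: it was −0.75 without WT 1, 0.29 without WT 2, 0.040 without KO 1 and −0.53 without KO 2. The list passed without WT 1 (lower, adjusted p = 6.5e-29) and without WT 2 (higher, 1.1e-16). Reg3b differed by −1.56 (SE 1.32) and Reg3g by −1.36 (SE 1.37), and without WT 2 by 0.75 and 1.22. The median was −0.04 for 12 T cell markers (adjusted p = 0.58), of which the adaptor gene Lat (0.86, SE 0.20) passed over the list alone. It was also −0.04 for 17 stromal, endothelial and glial markers (adjusted p = 0.89). Single arrays turned the sign of both: the T cell median was 0.028 without WT 1 and −0.18 without WT 2. The stromal median was 0.032 without WT 1 and −0.14 without KO 1 or without KO 2. The 23 genes around Nr1d1 on chromosome 11 had a median of 0.01 (−0.13 without WT 2, adjusted p = 0.89), with Ccr7 and Thra lower and Ikzf3 higher over the list alone. Over all genes 0 members of these lists passed. Of mast and red cell markers 3 genes were measured, too few for a test, and the mast cell protease gene Cpa3 fell by 1.69 (SE 0.25, adjusted p = 0.0495). That call was lost with a second quantile normalisation, without the filter, with the mean of probe sets and with log2(value + 16). Camera's direction, which is relative to all other genes, was up for 7 lists with a negative median: mitochondrial biogenesis, glycolysis, fatty acid oxidation, aryl hydrocarbon receptor targets, survival, T cell and stromal markers. For the type 17 regulators and the Nr1d1 neighbours the median was positive and the mean negative. For the stromal markers the mean was positive.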

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

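The tests on probes shared between Il22 and Iltifb and on B cells or dendritic cells were chosen after the results they measure had been seen, and the others before.

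Of 2409 tested probe sets without a single gene symbol, which the comparison of genes left out, 1 passed the threshold, and it stood out as a signal in data that the comparison did not use. Probe set 17284354, annotated to several immunoglobulin heavy-chain genes, was lower in KO arrays by −3.38 (SE 0.35, limma adjusted p = 0.033), with log2 values of 10.38 in WT 1, 9.41 in WT 2, 6.82 in KO 1 and 6.20 in KO 2.

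Several genes typical of other cell types were lower in KO arrays, and cells of other types in the WT sorts are candidate explanations. Of the called genes, Bank1 of B cell receptor signalling (2.17) and the T cell receptor segment Trgv5 (1.23) went the other way and were higher in KO arrays. Whether other cells in the KO sorts carried these was not tested. Epithelial cells, which the gate on CD45 and CD90.2 should remove, are a candidate source of S100g, Plb1 and Prss2. These genes differed by −2.89, −2.47 and −1.996, and the epithelial list had a median of −0.22 (SE 0.14, with genes taken as independent). Single arrays set that median (−0.75 without WT 1, −0.53 without KO 2 and 0.29 without WT 2), so it cannot decide. Reg3b at 11.31 in WT 2 and 8.74 in KO 2 against 6.69 in WT 1 leaves epithelial RNA in WT 2 and KO 2 possible. Reg3g, Fabp6 and Clca1 were also higher in WT 2 and KO 2 than in WT 1. S100g measured 9.42 in WT 1, 8.96 in WT 2 and 6.23 in KO 2, and Plb1 8.79, 8.57 and 6.22. Prss2 measured 7.28, 7.22 and 5.52. These genes followed genotype and not the Reg3b signal, which argues against cells with that signal as their source. Epithelial cells without it stay open. For NKp46+ cells, which the gate excluded, as the source of Ncr1, a median of −0.095 (SE 0.14) over the other 22 genes argues against a fall of that list as a whole. It took in dim genes (median 7.13 in WT, against 7.28 for all genes tested), whose fall would be understated, so it cannot exclude such cells. Xcl1 (−1.32), Ccl5 (−0.91) and Klrb1c (−0.87, but −0.26 without KO 1) were lower, and Klrk1 (1.03) was higher. B or plasma cells, in a gate that excluded CD19, and dendritic cells, most of which the gate on CD90.2 would remove, stay open for the class II genes. Their markers had a joint median of −0.27 (SE 0.10) against −0.88, but the B cell list alone reached −0.53 with the filter at the 50th percentile. Of the 16 markers with a difference above −0.3, 11 lay under the median intensity of all genes tested (log2 7.28). The immunoglobulin heavy-chain probe set differed by −3.38 and Jchain by −1.65, which goes with such cells in the WT sorts. Within WT, though, both were higher in WT 1 (10.38 and 8.13) than in WT 2 (9.41 and 6.76). H2-Eb1 went the other way (10.14 in WT 1 and 10.99 in WT 2), as did H2-DMb2, H2-Oa, H2-Ab1 and Blk. So the heavy-chain and Jchain signals did not track the class II genes within WT. The B cell genes Ms4a1, Cd79a, Cr2, Fcer2a and Ebf1, named outside the rule, lay under the filter and were not tested. In the B and plasma cell list 8 genes were negative and 2 positive. An effect of Nr1d1 loss on the ILC3 themselves is open too and was not separated from a change in which cells the gate held.

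Iltifb rose while Il22 did not. Il22 differed by −0.79 (SE 0.29), and by −0.32 without KO 2, but that value is part of the pattern and does not test probes shared between these copies. In WT 1 and WT 2 the Iltifb probe set had intensities of 18.4 and 33.6, where that of Il22 had 2267 and 2589. These levels argue against an Iltifb probe set that reads Il22 transcripts. Whether the Il22 probe set reads Iltifb transcripts stays open. A haplotype difference around both genes cannot be told apart from an effect of Nr1d1 loss: 4 of the 50 nearest measured genes differed at an unadjusted p under 0.05, where 4.67 are expected (exact hypergeometric p = 0.70), and too few genes lie there to exclude a short stretch.

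Cacna1g, the gene with the smallest p, lies on chromosome 11 like Nr1d1. On that whole chromosome 3 genes were called, where 3.85 are expected. Sequence of another strain kept beside the targeted allele may change genes there, and 1 of the 200 nearest measured genes was called, Cacna1g itself, where 0.60 are expected (exact hypergeometric p = 0.45). The test cannot exclude such an effect on Cacna1g alone.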

How the results depend on the processing

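All alternatives were planned. All 46 called genes kept their sign in each refitted setting where they were tested, and 12 stayed past the threshold in all 14. The count of called genes (higher and lower) was 24 (10 and 14) with a second quantile normalisation, 12 (4 and 8) without the filter, 91 (33 and 58) at an adjusted p of 0.10, 22 (8 and 14) with all probe sets tested alone, and 0 (0 and 0) with an unmoderated linear model, which gave 978 genes at an unadjusted p under 0.05. Centring moved the median of all genes from −0.08 to 0.03 and gave 64 genes, 31 of them higher. Leaving out 1 array, where the lone array is assumed to vary like the other group, gave 79 to 1800 genes (41 to 454 higher, 38 to 1346 lower, with more higher than lower without WT 2 and without KO 1) and 165 to 538 separated genes at least 2-fold apart.

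Nr1d1 passed at −1.16 with the filter at the 50th percentile (adjusted p = 0.032), the intensity trend (0.029), the robust option (0.041) and array weights (0.037), and at −1.14 with log2(value + 16) (0.042). Without single arrays it ranged from −1.21 to −1.11. Arntl ranged from −0.085 to 0.45, Reg3b from −3.87 to 0.75 and Reg3g from −3.94 to 1.22 without single arrays, where fewer samples let 1 array decide. The number of gene lists called was 11 without the filter, 0 with an estimated correlation, 0 with fry (2 at an unadjusted p under 0.05) and 7 to 13 without single arrays. The cause of the other changes was not tested.

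With the replicate number as a block (a paired fit), 485 genes passed, 152 higher and 333 lower, all 46 among them, with Nr1d1 at −1.16 (adjusted p = 1.3e-04) and 11 lists, the 7 and those of B and plasma cells (0.011), myeloid cells (0.0498), interferon (0.037) and chemokine receptors (0.030). Deviations of same-numbered arrays correlated with r = 0.19 over only 2 pairs, so the numbers were not taken to pair the samples. The 4 arrays allow 3 splits, too few for a share under 0.05: the real one gave 46 genes and the highest other 1. The other splits put 1 WT and 1 KO array in each group. Genotype differences then add to the spread within groups and lower the count, so these splits do not show what chance gives. No background values were at hand, so what signal limits was not measured.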

Other observations

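Some called genes outside the naming rule are given here, chosen after their values were seen. Pdcd1, which encodes the inhibitory receptor PD-1, fell by 1.55, and Cd7, a lymphoid surface glycoprotein, by 1.23. Cd7 measured 12.67 and 12.68 in WT against 11.38 and 11.50 in KO arrays. Trgv5, a T cell receptor γ variable segment, rose by 1.23, and Pde2a, a phosphodiesterase that breaks down cyclic nucleotides, by 1.33. Of the 46 called genes, 2 had names that the rule left out, the small RNA genes Mir5123 (2.38) and Snord82 (2.34).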
